A study of Homo sapiens with 6 samples.

How the data were processed

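RNA was sequenced from HEK293T cells, a human embryonic kidney cell line that carries the SV40 large T antigen, a viral protein that binds p53. NBDY is a human microprotein that binds EDC4, a scaffold of the mRNA decapping complex in P-bodies, which are cytoplasmic granules of mRNA and mRNA decay proteins. Per the labels, residues 22 to 41 of NBDY were overexpressed in 3 libraries, and 3 further libraries were controls. The stated purpose was to disturb P-bodies and to follow the pathways that respond, tumour suppression among them. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

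Per the labels' protocols, mRNA was taken from total RNA with oligo-dT beads and made into libraries with the KAPA mRNA HyperPrep kit. The deposited values are raw read counts per gene, made by the authors with HISAT alignment and featureCounts counting on GRCh38, per the submitters' processing notes. Versions, the annotation release, the strand setting and the handling of reads with several alignments were not given in the sources used here. Reads of overlapping genes, of antisense partners and of near-identical copies therefore cannot be assigned with certainty, and values of such genes are uncertain. The table's header names EGFP for the control columns, while the labels say only control. Those columns were taken as the control libraries because control is the only other group and the numbers match.

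The table holds 58884 Ensembl gene identifiers. Symbols were found for 58472 of them in a gene name table, and 58611 are in GENCODE release 29 on GRCh38, which gave positions, gene types, and the length and GC content of the longest transcript. Identifiers outside that release held at most 0.0087% of the counts of any library. Library totals ran from 15336504 to 21548581 counts. The common dispersion fitted by edgeR corresponds to a coefficient of variation of 13.7% between libraries of a group. Within a group, the correlation of log2 CPM between libraries was 0.980 to 0.989 across genes. Squared count differences were 11.6 to 29.8 times those that sampling noise gives (chi-square per degree of freedom), so no pair looked like 1 library deposited again. This does not show that the libraries came from separate cultures.

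Groups were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings, libraries were scaled by TMM, and the quasi-likelihood test was fitted on group alone, with Benjamini-Hochberg adjustment and a threshold of 0.05. All edgeR p-values given are adjusted unless stated. Standard errors are those of the fitted log2 fold change. CPM values are counts scaled to a common library size, with the SD over 3 libraries. Shares of counts were compared with two-sided exact permutation tests, in which 3 libraries against 3 cannot give a p below 0.1.

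A set of 27 gene lists was fixed before the data were examined, along with the tests and the rule for naming genes. The lists on P-body components, p53 target genes and tumour suppressor genes follow the series' stated subject, and the others cover mRNA decay, stress, cell cycle, metabolism, chromatin and markers of other cell types. Of these, 26 had at least 3 tested members and were tested with camera from limma 3.58.1, which asks whether a list moved against the other genes, with a preset correlation between genes of 0.01 and adjustment over the lists. With an estimated correlation, only the p53 target list of the 12 lists that passed camera still passed. That setting also bases the test on the residual degrees of freedom, which are few with 6 libraries. A call lost there can therefore reflect either change. For the p53 list the estimate was 0.0045, below the preset, yet the unadjusted camera p rose from 5.26e-11 to 0.00171. The fry test, which asks whether a list's genes move one way on balance, stands beside camera. Named genes were the 10 with the largest increase and the 10 with the largest decrease among called genes with a symbol, a mean of at least 5 CPM and no overlap between the groups. They also include 10 genes fixed by name, and up to 4 members with the smallest p of each list.

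Replicate numbers come from the sample titles. Deviations from the group means correlated at 0.13, 0.36 and 0.31 between the control and NBDY libraries of the same number, all above the limit of 0.1 set for calling libraries paired. The numbers therefore paired the libraries, although no label says what the libraries of a number share. The fit with the number as a block is given where it changed a call or moved a count by over 1.5 times.

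The edgeR test was tested on simulated data for this comparison, with 200 genes changed among real means, dispersions and depths. Of 17435 genes tested there, it recovered 23.9% of the changed genes at a log2 change of 0.5, 71.4% at 1 and 100% at 2, and 11 of its 136 calls were false. Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, the block, each library left out in turn and a GC and length correction.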

Results

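Read counts per gene were deposited for 6 HEK293T libraries, 3 with NBDY residues 22 to 41 overexpressed (NBDY 22-41) and 3 controls. HEK293T is a line derived from human embryonic kidney cells, and NBDY is a microprotein that binds the decapping scaffold EDC4 and acts on P-bodies, cytoplasmic granules of mRNA and decay factors. The NBDY libraries held 20318269, 15336504 and 18998407 counts and the control libraries 21548581, 16566284 and 20418168. After the filter on low counts, 17804 genes were tested. The design gives 1 comparison, NBDY 22-41 against control, which per the series' stated purpose asks how transcript levels respond to a disturbance of P-bodies. P-bodies themselves are not measured in these files.

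INHBE, which encodes a subunit of the activin family of secreted factors, stood at 55.2 ± 1.54 CPM with NBDY 22-41 and 6.46 ± 0.21 CPM in controls (SD, n = 3), 8.54-fold higher. The anion channel gene BEST1 was 9.07-fold higher (18.4 ± 2.22 against 1.99 ± 0.764 CPM), and LIF, a cytokine gene and p53 target, was 4.87-fold higher (36.9 ± 11.8 against 7.53 ± 1.54 CPM). The neuronal transcription factor NHLH2 (log2 fold change 2.59), the ETS factor ETV7 (2.48), the cell adhesion gene NECTIN4 (2.26) and CYP4F3 (2.75), a fatty acid hydroxylase, also rose. Of the genes that fell, G0S2, an inhibitor of the lipase ATGL, had the largest log2 fold change, -2.90, from 53.1 ± 36.7 to 7.08 ± 1.44 CPM; its control libraries ranged from 12.1 to 82.6 CPM. H6PD, the hexose-6-phosphate dehydrogenase of the endoplasmic reticulum (-1.42), the epoxide hydrolase EPHX2 (-1.16), the B-cell factor family member EBF4 (-1.25) and the collagen COL13A1 (-1.13) fell as well. These genes passed the edgeR test with adjusted p from 1.09e-07 for INHBE to 0.00858 for EPHX2.

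Among called genes with a mean of at least 5 CPM and no overlap between the groups, the other genes with the largest increases were FMNL1-DT (2.95), IRS3P (2.77) and KLKP1 (2.52), and those with the largest decreases were ZNF710-AS1 (-1.30), CELSR1P1 (-1.28), SLC66A3 (-1.17), STUM (-1.15) and TMEM143 (-1.14), all as log2 fold changes. FMNL1-DT and ZNF710-AS1 are annotated as antisense transcripts, and IRS3P, KLKP1 and CELSR1P1 as pseudogenes, so their reads may belong to other genes. In GRCh38 coordinates of GENCODE release 29, INHBE lies on chromosome 12 from 57452323 to 57459280, BEST1 on chromosome 11 from 61949821 to 61965515, LIF on chromosome 22 from 30240447 to 30246851, and G0S2 on chromosome 1 from 209675420 to 209676388. Counts cover the whole gene and do not separate exons or untranslated regions.

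In all, 2288 genes (12.9% of those tested) were higher and 1545 (8.68%) were lower with NBDY 22-41 at an edgeR adjusted p below 0.05. Increases were larger than decreases: a log2 change of at least 1 was reached by 806 of the genes that rose and by 138 of those that fell. Of 13803 protein-coding genes, 1778 rose and 1419 fell. The surplus of increases was larger among 491 processed pseudogenes (65 rose, 6 fell) and 1232 antisense genes (135 rose, 41 fell). What this surplus reflects was not tested. The 3 libraries of each group did not overlap at 39.2% of tested genes, where chance gives 10%. With the replicate number as a block, 4009 genes were higher and 3906 lower, and all 3833 genes called without the block kept their call and direction. The counts were smaller without control replicate 1 (1261 higher, 586 lower), without NBDY replicate 1 (1406 and 603) and, for lower genes, without control replicate 2 (843).

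**Figure D1:**
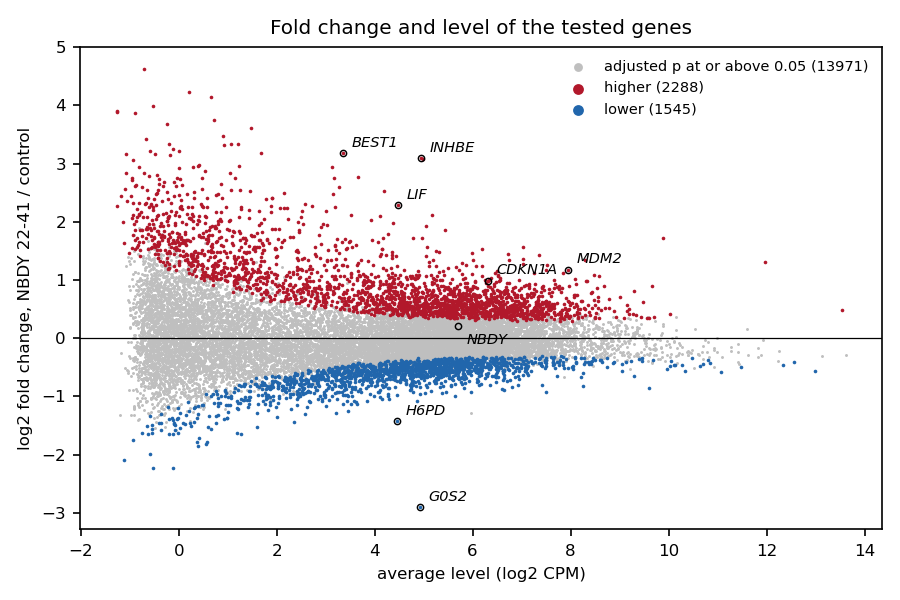
Log2 fold change (NBDY 22-41 over control) of each tested gene against its average level in log2 CPM over the 6 libraries, with 2288 higher genes in red, 1545 lower genes in blue and the others in grey. INHBE, BEST1 and LIF lie at the upper edge for their level and G0S2 at the lower, some genes of low level rose more, and NBDY lies at a log2 fold change of 0.22 among genes that did not pass the test.

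The first question was what happened to the P-body genes themselves. NBDY transcripts stood at 55.8 ± 6.11 CPM with NBDY 22-41 and 48.0 ± 1.48 CPM in controls, a log2 fold change of 0.22 ± 0.117 (SE; edgeR adjusted p = 0.204, with the replicate block 0.0495). Whether reads of the overexpressed fragment were aligned to and counted for NBDY (ENSG00000204272, chromosome X from 56729241 to 56818380) is not given in the sources used here, so this count does not check the labels. EDC4, the decapping scaffold that NBDY binds (ENSG00000038358, chromosome 16 from 67873023 to 67884503), had a log2 fold change of 0.27 ± 0.177 (adjusted p = 0.290, with the block 0.00705). The helicase DDX6 (-0.02 ± 0.122), the decapping enzyme DCP2 (-0.09 ± 0.122) and the translational repressor LSM14A (0.13 ± 0.107) did not pass with or without the block. The decapping activator DCP1A (0.22; adjusted p = 0.154) and the 5'-to-3' exonuclease XRN1 (0.38; 0.103) passed with the block (0.00819 and 3.52e-04), and XRN1 also passed without NBDY replicate 2 (0.0150) and with the GC and length correction (0.0116).

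Of 39 P-body genes tested, 6 rose (15.4%, against 12.9% of all tested genes) and the other 33 did not pass. Adjusting p over the list alone gave the same 6. They were led by ZFP36, a protein that binds AU-rich elements and recruits deadenylases (4.05 ± 0.123 to 10.5 ± 0.46 CPM; log2 fold change 1.38 ± 0.166, edgeR adjusted p = 2.58e-04), and by ATXN2L (0.57; 0.0066). LSM1 (0.49; 0.0175), a subunit of the ring that binds deadenylated mRNA, and the microRNA effector TNRC6A (0.41; 0.0209) followed. The LSM1 call ended without control replicate 1 (0.0870) or NBDY replicate 1 (0.0577), and 38.5% of its exon bases overlap another gene. The TNRC6A call ended without control replicate 1 (0.101) or 2 (0.0988) or NBDY replicate 1 (0.0623) or 3 (0.0525). As a list, P-body genes had a median log2 fold change of 0.10 and did not pass camera (adjusted p = 0.228), while fry gave an adjusted p of 0.0301. The count of higher genes was 2 without control replicate 1 or NBDY replicate 1 and 3 without control replicate 2, and with the block 14 were higher and 5 lower. Without NBDY replicate 2, 2 P-body genes were lower, a count also given by upper quartile scaling and by DESeq2, and with the GC and length correction 9 were higher and 4 lower.

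Genes of mRNA decay and of stress granules rose in shares near that of all tested genes (12.9%). The shares were 15.8% of decay enzymes, 18.8% of nonsense-mediated decay factors and 11.1% of stress granule genes. Among 38 deadenylation and decay enzymes, 6 rose and 1, DIS3L (-0.35, named after its value was seen), fell (5 higher when adjusted over the list alone), led by the CCR4-NOT subunits CNOT4 (log2 fold change 0.94, edgeR adjusted p = 1.51e-04) and CNOT3 (0.84; 4.45e-04) and the exosome subunit EXOSC9 (0.84; 4.03e-04). Among 16 nonsense-mediated decay factors, 3 rose, also 3 when adjusted over the list alone: SMG8 (0.72; 0.00883), SMG5 (0.56; 0.00953) and UPF2 (0.41; 0.0259). Among 18 stress granule genes, ATXN2 (0.50; 0.00589) and TIAL1 (0.30; 0.0463) rose and HDAC6 (-0.46; 0.0181) fell, and 1 was higher and 1 lower when adjusted over the list alone. None of these 3 lists passed camera (adjusted p = 0.491, 0.0810 and 0.732), although fry, which does not compare a list with other genes, gave 0.0101 and 0.0129 for the first 2; with the block, the nonsense-mediated decay list passed (0.0357), but not with the block and an estimated correlation (adjusted p = 0.469), and the counts higher and lower were 11 and 7, 9 and 1, and 8 and 5. Without control replicate 1 the counts higher were 3, 1 and 1, and the calls of SMG5 (0.0617), UPF2 (0.0966), HDAC6 (0.0589) and TIAL1 (0.153) ended. The UPF2 call also ended without control replicate 3 (0.0838) or NBDY replicate 1 (0.0812) or 2 (0.0675), the HDAC6 call without control replicate 2 (0.0607), and the TIAL1 call without any 1 library except NBDY replicate 2, at adjusted p up to 0.172. With the GC and length correction the UPF2 (0.0679) and TIAL1 (0.0665) calls ended, and that of TIAL1 ended with upper quartile scaling (0.0553) and without the low-count filter (0.172). Without control replicate 2 the count of higher decay enzymes was 3, DIS3L was not called without control replicate 1 or 2 or NBDY replicate 1, and without NBDY replicate 3 that of nonsense-mediated decay factors was 5.

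The second question concerned p53 and tumour suppressor genes. CDKN1A, the p21 cell cycle inhibitor and a classical p53 target (ENSG00000124762, chromosome 6 from 36676460 to 36687339), rose 1.99-fold, from 52.8 ± 3.43 to 105 ± 0.893 CPM (log2 fold change 0.99 ± 0.106, edgeR adjusted p = 1.35e-04). MDM2, the ubiquitin ligase that degrades p53 (ENSG00000135679, chromosome 12 from 68808176 to 68850686), rose 2.26-fold, from 152 ± 36.7 to 343 ± 104 CPM (1.18 ± 0.206; 0.00252). The kinase genes PLK2 (log2 fold change 1.72) and PLK3 (2.09), the antiproliferative gene BTG2 (1.35) and the stress cytokine GDF15 (2.11) rose with adjusted p of 2.18e-05 to 3.45e-05.

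Of 72 p53 target genes tested, 43 rose and 4 fell, and 45 rose and 5 fell when adjusted over the list alone. The 4 that fell were STEAP3 (-0.55), CCNG1 (-0.44), PERP (-0.38) and ORAI3 (-0.82), named after their values were seen; 52.9% of the exon bases of ORAI3 overlap another gene. The list's median log2 fold change was 0.45, and it passed camera (adjusted p = 6.83e-10) and also passed with an estimated correlation (adjusted p = 0.0446). With both the replicate block and an estimated correlation it no longer passed (adjusted p = 0.372). In that setting, which leaves few residual degrees of freedom, all 12 lists that passed camera lost their call. The loss therefore says little about the p53 list in particular. The count of lower targets was 1 without control replicate 1 or NBDY replicate 1.

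Of 41 tumour suppressor genes tested, 12 rose and the other 29 did not pass, with 12 also when adjusted over the list alone. Besides BTG2 and CDKN1A, which the p53 list also holds, they included FBXW7, a substrate adaptor of a ubiquitin ligase (58.8 ± 1.75 to 123 ± 10.2 CPM; log2 fold change 1.07, edgeR adjusted p = 1.01e-04), and the AKT repressor PHLDA3 (1.22; 1.65e-04), again a p53 target. The list's median was 0.04 and it did not pass camera (adjusted p = 0.107), although it did without NBDY replicate 2 (0.0468) and with the GC and length correction (0.0406), and fry gave 0.0184. It did not pass with an estimated correlation (adjusted p = 0.587) or with the correction and the block together (0.0583). The count of higher genes was 5 without control replicate 1, 6 without control replicate 2 and 7 without NBDY replicate 1 or 3, and 8 genes were lower with the block.

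**Figure D2:**
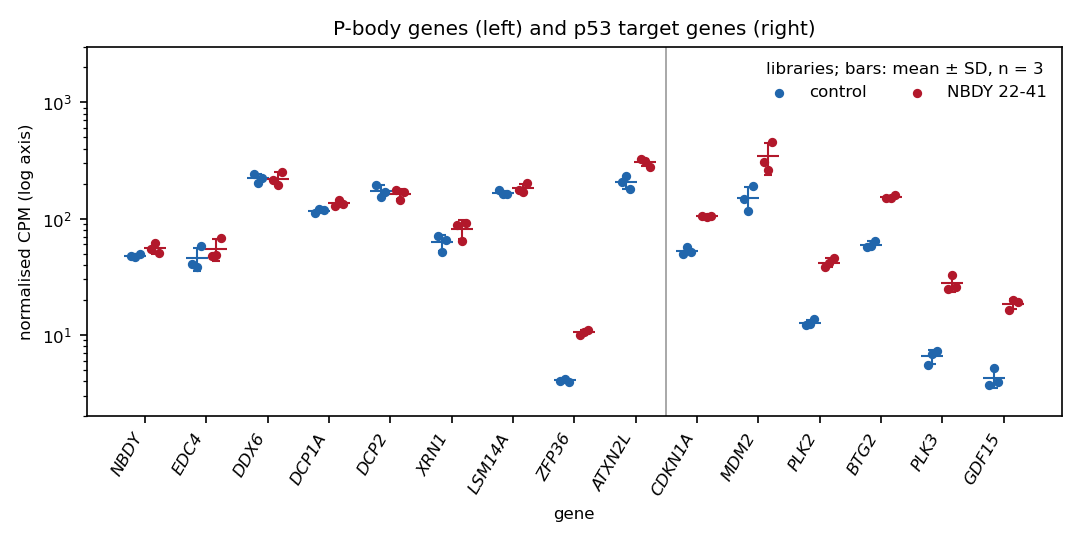
Normalised CPM on a log axis of P-body genes (left of the line) and of p53 target genes (right), with a point per library and bars for the mean ± SD of 3 libraries. All 3 NBDY 22-41 libraries (red) lie above all 3 control libraries (blue) for CDKN1A, MDM2, PLK2, BTG2, PLK3 and GDF15, and also for the P-body gene ZFP36. The groups overlap for EDC4, DDX6, DCP2, XRN1 and LSM14A.

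**Figure D3:**
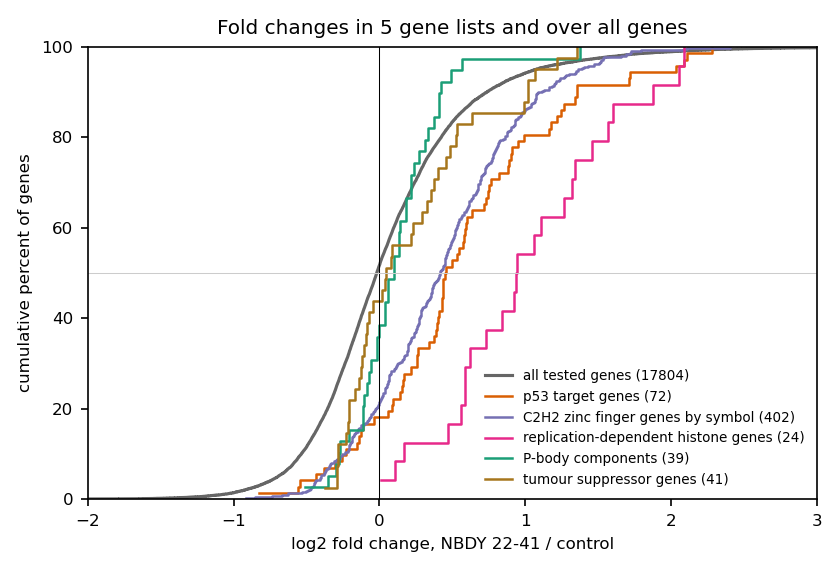
Cumulative percent of genes against log2 fold change (NBDY 22-41 over control) for 5 gene lists and for all 17804 tested genes. The curves of p53 targets (median 0.45), zinc finger genes (0.42) and histone genes (0.94) lie to the right of the curve of all genes, while those of P-body genes (0.10) and tumour suppressors (0.04) lie close to it in the middle.

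Part of the DNA replication genes and most measured replication-dependent histone genes rose, while mitotic genes that passed went both ways. Of 55 G1/S and replication genes, 21 rose and 2 fell (22 and 3 adjusted over the list alone), among them the origin licensing factor CDC6 (2.01-fold; log2 fold change 1.01, edgeR adjusted p = 1.07e-04), the exonuclease EXO1 (0.86) and the checkpoint kinase CHEK1 (0.84). Of 24 histone genes with enough counts, 16 rose and the other 8 did not pass (19 rose when adjusted over the list alone), with H3C6 at 17.3 ± 2.69 against 5.82 ± 0.297 CPM and H4C5 at 6.06 ± 0.7 against 1.65 ± 0.296 CPM. Of 55 G2/M genes, 5 rose and 4 fell (1 and 1 adjusted over the list alone), led by the condensin subunit NCAPG (0.75; 33.1% of its exon bases overlap another gene) and the phosphatase CDC25B (-0.56). The medians were 0.21, 0.94 and -0.06, with camera adjusted p of 0.00156, 8.26e-09 and 0.678; with an estimated correlation the first 2 lists did not pass (adjusted p = 0.234 for each). The G1/S count of higher genes was 11 without control replicate 1. With the block, 9 G1/S genes were lower and 15 G2/M genes were higher and 19 lower, while 1 or 2 G2/M genes were higher without any 1 library except NBDY replicate 2. Without any 1 library except NBDY replicate 3, no more than 1 G1/S gene and no more than 2 G2/M genes were lower.

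Apoptosis genes showed no common direction. Of 39 tested, 6 rose and 3 fell (7 and 4 adjusted over the list alone): the death receptor FAS rose (log2 fold change 1.25, edgeR adjusted p = 3.68e-04), as did the caspase inhibitor BIRC3 (2.01; 0.0013), while the pro-apoptotic genes BOK (-1.79; 0.00517) and HRK (-1.08; 0.00589) fell. BIRC3 and BOK were counted at no more than 3.17 CPM in either group. The list did not pass camera (adjusted p = 0.593), 3 genes were higher without control replicate 1 or NBDY replicate 1, and with the block 17 were higher and 8 lower.

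Far more immediate early genes, which respond to growth factors and stress, rose than fell. Of 43 tested, 21 rose and 2 fell (24 and 2 adjusted over the list alone), with FOSL1 at a log2 fold change of 2.02 (edgeR adjusted p = 2.18e-05), PPP1R15A, which directs dephosphorylation of eIF2alpha, at 1.56 (3.1e-05) and ATF3 at 1.12 (6.6e-05); MYC (-0.72) was among those that fell. MYC was named after its value was seen, and 1 gene was lower without control replicate 3 or NBDY replicate 1. The list's median was 0.53 and it passed camera (adjusted p = 1.19e-07), but not with an estimated correlation (adjusted p = 0.234). Of 19 NF-kB and inflammatory genes, 3 rose (2 adjusted over the list alone): LIF, BIRC3 and NFKBIE (0.59; 0.0413), and camera gave an adjusted p of 0.491. The NFKBIE call ended without control replicate 1 (0.162) or 2 (0.0662) or NBDY replicate 1 (0.101) or 2 (0.0859), and with upper quartile scaling (0.0502). The mitochondrial superoxide dismutase SOD2, also on the list, had a log2 fold change of -0.51 that did not pass (0.0557). It was called lower with the block (7.57e-06), with upper quartile scaling (0.0329), without the low-count filter (4.38e-04), by DESeq2 (0.0241) and limma-voom (0.0483), with the GC and length correction (0.00618) and without control replicate 2 (0.0367) or NBDY replicate 3 (0.00476). With the block, 4 genes of the list were higher and 2 lower.

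Stress pathways were split. Of 45 integrated stress response genes, 14 rose and 9 fell (15 and 10 adjusted over the list alone): FGF21 (log2 fold change 3.32, from 0.317 to 3.31 CPM), GDF15, PPP1R15A and ATF3 were among those that rose. The list's median was -0.03 while its mean and camera pointed up (camera adjusted p = 0.491). Of 30 heat shock genes, 7 rose, also 7 when adjusted over the list alone, led by HSPA6 (3.18; 0.609 ± 0.104 to 5.66 ± 1.4 CPM), the heme oxygenase HMOX1 (1.56) and the autophagy receptor SQSTM1 (0.67). Of 35 unfolded protein response genes, 4 rose and 1, CREB3L2 (-0.40, named after its value was seen), fell (3 higher adjusted over the list alone), with XBP1 (0.71) and the kinase EIF2AK3 (0.64) in front. Camera gave adjusted p of 0.0573 for heat shock and 0.758 for the unfolded protein response. The heat shock list passed with the block (0.0374), with a filter on mean CPM or with the GC and length correction (0.0406 for each) and without control replicate 3 (0.0190) or NBDY replicate 1 (0.0351), and fry gave 0.0323. With an estimated correlation it did not pass with the block (adjusted p = 0.543) or without it (adjusted p = 0.587).

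These stress counts moved with single libraries. Without control replicate 1 or NBDY replicate 1, 9 integrated stress response genes were higher and 3 lower, 4 heat shock genes were higher and 2 unfolded protein response genes were higher. Without control replicate 3, 9 integrated stress response genes were higher, and without control replicate 2, 5 were lower and 2 unfolded protein response genes were higher. CREB3L2 was called lower in none of the fits without control replicate 1, 2 or 3 or NBDY replicate 1 or 2. With the block, 18 integrated stress response genes, 7 heat shock genes and 11 unfolded protein response genes were lower, and 13 heat shock genes were higher.

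Interferon-stimulated genes that passed the test were mostly lower. Of 34 tested, 5 fell and 1 rose (8 and 1 adjusted over the list alone): IFI6 fell (log2 fold change -0.83, edgeR adjusted p = 0.00738), as did IFIT1 (-0.79; 0.0111) and the transcription factor STAT2 (-0.49; 0.0188), while the exonuclease ISG20 rose (1.71; 0.00153). The median was -0.35 and the list passed camera (adjusted p = 0.0054), but not with an estimated correlation (adjusted p = 0.234). Without control replicate 1 or NBDY replicate 1, 1 gene was lower, which ended the calls of IFIT1 (0.0559 and 0.0512) and STAT2 (0.0768 and 0.0738); with the block, 12 were lower and 3 higher.

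Without the replicate block, several genes of glycolysis and a few of cholesterol synthesis fell. Of 37 glycolysis and hypoxia genes, 12 fell and 1, the lactate transporter SLC16A3 (0.94, named after its value was seen), rose (15 and 1 adjusted over the list alone). The 3 phosphofructokinase genes PFKM (log2 fold change -0.54), PFKP (-0.60) and PFKL (-0.56) and the hypoxia marker NDRG1 (-0.89; 130 ± 7.55 to 70.1 ± 11.2 CPM) were among them, with edgeR adjusted p of 7.46e-04 to 0.00612. Of 26 cholesterol synthesis genes, 3 fell, also 3 when adjusted over the list alone: INSIG1 (-0.60; 0.0052), LSS (-0.54; 0.00875) and IDI1 (-0.41; 0.0127). The medians were -0.26 and -0.19 and both lists passed camera (adjusted p = 3.29e-04 and 0.0171), but not with an estimated correlation (adjusted p = 0.234 and 0.308). Without 1 library the glycolysis count of lower genes was 7 (control replicate 1), 6 (control replicate 2) or 4 (NBDY replicate 1), the cholesterol list did not pass camera without control replicate 3 (0.0891), and the IDI1 call ended without control replicate 1 (0.0563) or NBDY replicate 1 (0.0510). SLC16A3 was not called by DESeq2 or without any 1 library except NBDY replicate 3. With the block, 24 glycolysis genes were lower and 4 higher, and 11 cholesterol genes were lower.

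How many respiratory chain genes were called lower depended on the fit: few without the replicate block and most with it. Of all tested genes, 8.68% were lower without the block. Of 13 mitochondrially encoded protein genes, 3 fell, also 3 when adjusted over the list alone: MT-CO2 (log2 fold change -0.45, edgeR adjusted p = 0.0133), MT-CO3 (-0.42; 0.0188) and MT-ND6 (-0.47; 0.0308). Of 75 nuclear genes of oxidative phosphorylation, 7 fell and 1, NDUFA13 (0.83; 0.0376), rose (2 lower adjusted over the list alone). NDUFA1 (-0.54; 0.00933) was among those that fell, and 44.5% of its exon bases overlap another gene. The medians were -0.30 and -0.21 and both lists passed camera (adjusted p = 0.00785 and 3.29e-04), but not with an estimated correlation (adjusted p = 0.587 and 0.658), and neither passed fry (0.157 and 0.263). The calls of MT-CO2, MT-CO3 and MT-ND6 ended without control replicate 1 (0.0593, 0.0685 and 0.143) or NBDY replicate 1 (0.0734, 0.0916 and 0.143), that of MT-ND6 also without NBDY replicate 2 (0.0569), and that of NDUFA1 without NBDY replicate 1 (0.0585). The NDUFA13 call ended with limma-voom and without any 1 library except NBDY replicate 3. Without NBDY replicate 1 the mitochondrially encoded list did not pass camera (0.0706). Without NBDY replicate 3, 10 mitochondrially encoded genes were lower; the nuclear count of lower genes ran from 1 without NBDY replicate 1 to 28 without NBDY replicate 2. With the block, 10 and 43 genes of the 2 lists were lower, as were 3906 of all 17804 tested genes. Without the low-count filter the 2 counts were 10 and 14. With the GC and length correction, 20 nuclear genes were lower.

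Ribosomal protein genes had a median log2 fold change of -0.29. Of 79 tested, 9 fell and 4 rose (8 and 4 adjusted over the list alone): RPS25 fell (-0.56, edgeR adjusted p = 0.0153), and RPS10 (1.42) and RPL17 (0.70) were among those that rose. RPS10 was counted at 27.5 ± 7.24 CPM with NBDY 22-41, and 39.4% of the exon bases of RPS10 and 35.3% of those of RPL17 overlap another gene; ribosomal protein genes also have many pseudogene copies, so these values are uncertain. The list passed camera (adjusted p = 4.44e-05), but not with an estimated correlation (adjusted p = 0.696), and it did not pass fry (0.328); its members varied together with a correlation of 0.849. The count of lower genes was 69 with the block, 45 without the low-count filter, 22 with the GC and length correction and 20 by DESeq2, and without 1 library it ran from 0 (control replicate 2 or NBDY replicate 1) to 48 (NBDY replicate 2), with 1 without control replicate 1, 18 without control replicate 3 and 4 without NBDY replicate 3. The RPS25 call ended without control replicate 1 (0.0577) or 2 (0.0514) or NBDY replicate 1 (0.0619).

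More extracellular matrix and TGF-beta genes fell than rose. Of 45 tested, 17 fell and 3 rose (19 and 3 adjusted over the list alone), including the laminin LAMA1 (43.0 ± 0.917 to 23.9 ± 2.38 CPM; log2 fold change -0.84, edgeR adjusted p = 7.86e-04), the collagen COL4A6 (-0.99; 0.00179) and ID4 (-0.87; 7.39e-04), an inhibitor of helix-loop-helix factors. SKIL, a repressor of SMAD signalling, rose (1.04; 2.47e-04). The median was -0.31 and the list passed camera (adjusted p = 4.03e-04), but not with an estimated correlation (adjusted p = 0.321). With the block, 27 were lower and 5 higher, and 1 was higher without control replicate 1 or 3 or NBDY replicate 3.

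Among the C2H2 zinc finger genes, a large family of mostly repressive transcription factors, far more rose than fell. Of 402 genes with ZNF symbols, 171 rose and 7 fell (192 and 13 adjusted over the list alone). ZNF461 went from 8.6 ± 0.297 to 29.9 ± 3.01 CPM (log2 fold change 1.80 ± 0.137, edgeR adjusted p = 2.18e-05), and ZNF416 (1.72), ZNF256 (1.69) and ZNF211 (1.41), all on chromosome 19, rose alike. The list's median was 0.42 and it passed camera (adjusted p = 6.12e-12), but not with an estimated correlation (adjusted p = 0.234). The count of lower genes was 34 with the block, 3 without control replicate 1 or NBDY replicate 1, and 4 without control replicate 2.

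**Figure D4:**
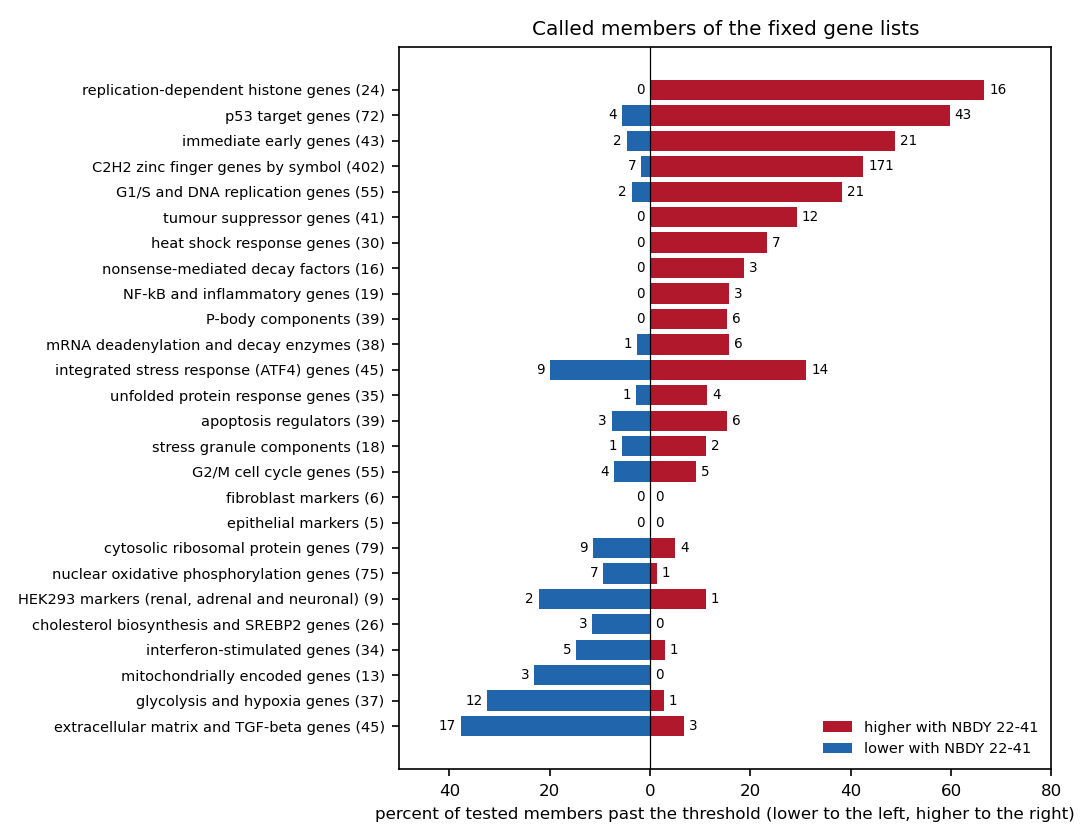
Percent of the tested members of each of 26 gene lists that were higher (red, to the right) or lower (blue, to the left) with NBDY 22-41 at an edgeR adjusted p below 0.05; numbers at the bars are gene counts and those in brackets are genes tested. Histone genes (16 of 24) and p53 targets (43 of 72) have the largest shares higher, and extracellular matrix genes (17 of 45) the largest share lower.

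Markers of other cell types were few. Of 6 fibroblast and 5 epithelial markers tested, 0 passed the edgeR test (2 and 1 had an unadjusted p below 0.05; DESeq2 called 0 and 0, limma-voom 1 and 0), with camera adjusted p of 0.411 and 0.678. With the block 3 fibroblast markers were lower, and without NBDY replicate 3 this count was 2. Of 13 blood cell markers, 2 had enough counts, too few for a list test; CD14 rose (log2 fold change 2.25, adjusted p = 7.40e-04). Of 9 renal, adrenal and neuronal markers known in HEK293 cells, the neurofilament genes NEFL (-0.63; 0.00183) and NEFM (-0.65; 0.00806) fell and NEFH (1.02; 0.0263) rose, the same 3 counts when adjusted over the list alone, with a camera adjusted p of 0.456. The NEFH call ended without any 1 library except NBDY replicate 3, at adjusted p of 0.0503 to 0.0935, and with DESeq2 (0.0534), and 38.9% of the exon bases of NEFM overlap another gene.

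The composition of the libraries differed in small shares. Protein-coding genes took 95.6% ± 0.133 of counts with NBDY 22-41 and 96.4% ± 0.247 in controls (SD, n = 3, exact permutation p = 0.1). Pseudogenes took 0.684% ± 0.0338 against 0.628% ± 0.018 (exact permutation p = 0.1), and long noncoding RNAs 1.65% ± 0.112 against 1.58% ± 0.136 (exact permutation p = 0.6). Genes with at least 1 count numbered 30080, 28686 and 29178 with NBDY 22-41 and 28756, 27157 and 28343 in controls. Histone transcripts took 0.0255% ± 0.0026 of counts with NBDY 22-41 and 0.0139% ± 0.0017 in controls (SD, n = 3; exact permutation p = 0.1, the smallest possible). Mitochondrial genes took 6.81% ± 0.737 against 7.14% ± 0.279 (exact permutation p = 0.5), which combined more mitochondrial rRNA (1.96% ± 0.0833 against 1.21% ± 0.0982; exact permutation p = 0.1) with a lower share of the other mitochondrial genes (4.85% ± 0.708 against 5.94% ± 0.33; exact permutation p = 0.2). Ribosomal protein genes took 7.09% ± 1.29 against 8.65% ± 1.31 (exact permutation p = 0.2). These tests ignore the replicate numbers. At numbers 1, 2 and 3 the ribosomal protein share was 8.45, 10.1 and 7.46% in controls. With NBDY 22-41 it was lower each time, at 7.03, 8.41 and 5.83%. The share of the other mitochondrial genes was also lower each time (4.44, 4.45 and 5.67% against 6.04, 5.57 and 6.20%). All mitochondrial genes together were lower at numbers 1 and 2 and higher at 3. Across 17765 genes, which are not independent replicates, log2 fold change and GC content had a Spearman correlation of -0.11, and log2 fold change and transcript length one of -0.04. Among protein-coding genes, the median log2 fold change was 0.03 in the tenth with the lowest GC content and -0.15 in the tenth with the highest.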

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

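The GC and length correction, alone or with the replicate block, and the block with an estimated correlation were added after seeing the data; the other settings were planned. Genes counted as higher and lower were 1083 and 376 at an adjusted p below 0.01, 806 and 138 at an absolute log2 fold change of at least 1, 4009 and 3906 with the replicate block, and 4281 and 4273 with the GC and length correction plus the block. With the correction alone, 2897 were higher and 2378 lower. Leaving out each library in turn gave 1261 to 2323 higher and 586 to 1638 lower genes. DESeq2 (2139 and 1714), limma-voom (2264 and 1509), 3 other scalings and 2 other filters kept both counts within 1.5 times, and DESeq2 shared 3548 of the 3833 calls. The cause of these shifts was not tested, apart from the stricter thresholds, which call fewer genes by construction. Smaller groups did not always call fewer genes: without NBDY replicate 2, 2323 were higher and 1638 lower, more than with all libraries.

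Lists were not tested on the DESeq2 and limma-voom fits. In the settings with a list test, the p53 list kept its direction and its call except with the replicate block with an estimated correlation (median log2 fold change 0.452, adjusted p = 0.372). In that setting no list passed camera. The tumour suppressor list, which did not pass camera, passed fry (median 0.0442, adjusted p = 0.0184) and passed with the GC and length correction (0.0561, adjusted p = 0.0406), but not with the correction and the block (adjusted p = 0.0583) or with an estimated correlation (adjusted p = 0.587). Its median ran from 0.0234 to 0.10 with a library left out, and it passed without NBDY replicate 2; over these settings its adjusted p ran from 0.0184 to 0.679. The P-body list passed fry alone (median 0.0987, adjusted p = 0.0301, in other settings up to 0.635). With the block, 10 of the 118 genes chosen by the naming rule became called, among them NBDY, EDC4, DCP1A, XRN1, RNPS1, SOD2, MT-ATP6 and SREBF2, as did the nonsense-mediated decay and heat shock lists, though not with the block and an estimated correlation (adjusted p = 0.469 and 0.543); it changed no other call of these genes or lists. No list and none of these genes reversed a call in any setting. With an estimated correlation, which also lowers the degrees of freedom of the test, 11 lists lost their camera call. The fry test called 5 lists that camera did not and lost 3: the ribosomal protein, mitochondrially encoded and nuclear oxidative phosphorylation lists. The GC and length correction alone raised the number of lower genes in several lists, to 20 from 7 for nuclear oxidative phosphorylation, 22 from 9 for ribosomal proteins, 10 from 4 for G2/M, 9 from 5 for interferon-stimulated, 7 from 3 for apoptosis and 16 from 7 for zinc finger genes, to 4 from 1 for decay enzyme, stress granule and unfolded protein response genes each, and 4 P-body genes were then lower. At a log2 change of 0.5, 23.9% of changed genes were recovered in simulated data with the depths and spread of these libraries. The simulation changed 200 genes, far fewer than the 3833 called here, and held no pairing. Because the adjustment of p depends on how many genes change, this rate need not hold for the real comparison. What depth alone limits was not separated from the spread between libraries.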

Other observations

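The tests of snoRNA host genes, of S phase and of the GC and length correction were chosen after results had been seen, and the test of reads shared between zinc finger paralogs replaced, after their rise was known, an earlier one that could not exclude shared reads. Several host genes of small nucleolar RNAs rose. Of 24 tested genes with SNHG symbols or GAS5, 10 rose, led by SNHG15 (log2 fold change 1.42, edgeR adjusted p = 5.17e-05), SNHG17 (1.45; 1.70e-04), SNHG11 (0.83; 0.00291) and SNHG9 (1.35; 0.00339). The family's median was 0.332, with a camera p of 0.00285 that became 0.262 with an estimated correlation. Transcripts of such host genes are known substrates of nonsense-mediated decay, and GAS5 itself stood at 0.37 (0.0568). Among annotated snoRNAs, 10 of 41 tested genes rose, with a median of 0.60.

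The rise of zinc finger genes extended past the ZNF symbols. Of 68 tested ZSCAN, ZKSCAN, ZBTB and ZFP genes, 23 rose and 2 fell, with a median of 0.2682 and a camera p of 2.98e-04 (0.198 with an estimated correlation). By family, the medians were 0.47 for 15 ZSCAN genes, 0.30 for 6 ZKSCAN, 0.19 for 34 ZBTB and 0.11 for 13 ZFP genes. The ZFP symbols take in ZFP36, the RNA-binding P-body gene named above. It is not a C2H2 factor and is among the 23 that rose. After a GC and length correction the ZNF median was 0.4051, and 1000 gene sets matched on GC content, length and level had medians of -0.14 to 0.03, below that of the list (0.42), which argues against such a bias as the whole cause. Among 178 ZNF genes with fewer than 5% of their 32-base windows in transcripts of other genes, the median was 0.4134 (quartiles 0.04 to 0.77; 80 rose and 4 fell), which argues against reads shared between paralogs. A response to NBDY 22-41 remains a hypothesis. The list's camera call was lost with an estimated correlation, a setting that also lowers the test's degrees of freedom.

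Histone transcripts and both mitochondrial rRNAs rose together: MT-RNR1 by a log2 fold change of 1.32 (edgeR adjusted p = 4.87e-05) and MT-RNR2 by 0.49 (0.0132). These RNAs lack long poly(A) tails, so more carry-through of such RNA in the oligo-dT step could raise them. A set of 28 other genes of such RNAs, 21 of them pseudogenes, had a median of 0.06542, below the bound of 0.3 set against this source, but the quartiles ran from -0.26 to 0.47 and the highest mean was 9.37 CPM. Of 41 snoRNAs 10 rose, and of 23 snRNAs, 22 of them in that set, edgeR called 0 (unadjusted p below 0.05 for 1; DESeq2 0, limma-voom 0), so the source cannot be told apart from a cellular change; this reading of the bound was made after the value was seen. For the histones but not the mitochondrial rRNAs, a larger share of cells in S phase is a candidate explanation: the median of the G1/S list exceeded that of the G2/M list by 0.264, though the G1/S call was lost with an estimated correlation (adjusted p = 0.234).

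The p53 targets share 11 members with the stress, immediate early, apoptosis, NF-kB and heat shock lists. Without them, the 61 remaining targets had a median of 0.4467 (35 rose, 4 fell; camera p = 5.23e-09, with an estimated correlation 0.00214), which argues against those members as the whole cause. After the GC and length correction the median of the list was 0.4564, and 1000 matched gene sets had medians of -0.24 to 0.18, which argues against that bias. Higher p53 activity with NBDY 22-41 is a candidate explanation, as a hypothesis found and tested on the same data. Explanations other than shared members and GC or length bias were not tested, and p53 protein was not measured here. HEK293T cells carry a viral large T antigen that binds p53. The call ended with the block and an estimated correlation together (adjusted p = 0.372), a setting in which no list passed camera.

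The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, called 2288 higher and 1545 lower genes by edgeR, and the highest number in any other split was 0 in either direction, with at most 1287 genes at an unadjusted p below 0.05 against 6415 in the real split. The replicate numbers pair the libraries: the real split and 3 others part every pair, and those 3 had 60 to 152 genes at an unadjusted p below 0.05, while the other 6 splits part 1 pair. For the p53 list, camera p with the preset correlation was 5.26e-11 in the real split. In the others, which still divide the groups 2 to 1, it ran from 5.63e-05 to 0.159. Most of these values were below 0.05 although 0 genes were called, so passing camera alone does not set the real split apart.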
